A study of Homo sapiens with 34 samples.

How the data were processed

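The series consists of 34 single cells, 23 of the prostate line 22Rv1 and 11 of the melanoma line A375, recovered after being added to blood. Per the labels' protocols, cells were frozen in a lysis buffer and made into Smart-seq3 libraries from polyadenylated RNA. The genome build was hg38 per the submitters' processing notes. The aligner, the counting tool, the annotation release, any filter on cells and the treatment of doublets are not given in the sources used here.

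The deposited UMI table holds whole-number counts of UMIs per cell code, summed over genes by the authors and not normalized. It gives 3 counts per cell per the file headers, namely for exons, for introns and for both together, which makes 102 values for 34 codes. The totals for exons and introns added up to slightly more than the deposited joint total in each of the 34 cells, by 0.034% to 0.48% of the joint total, so the joint total was used as the depth of a cell. The other file pairs 61598 gene identifiers with symbols and holds 0 columns of measurements. Of these identifiers, 61445 (99.8%) matched a current human gene table when the version suffix was dropped, and 20504 carried their own identifier in place of a symbol.

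Groups were taken from the sample titles. Each code was searched for in all labels of all 34 samples, and 0 were found, so no code was given to a cell line and no order or value was used in place of a label. The codes were taken to be the 34 labelled cells, which rests on their number alone. The comparisons fixed beforehand were the ratio of UMIs between lines, the intronic share per line, expression of genes by line and the share of cells with blood cell transcripts. These need a map from codes to lines, and the last 2 also need counts per gene, so they were replaced by a description over all cells. A total over all cells took the place of a total per line. The rule for naming genes gave no expression value where counts per gene were absent from the analysis. The 8 marker lists fixed beforehand (melanoma, prostate, epithelial, leukocyte, erythrocyte, platelet, proliferation and housekeeping) hold 59 genes, of which 59 occur in the gene dictionary. They received no value.

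For each cell the intronic share was the intronic UMIs divided by the joint total, with a 95% exact Clopper-Pearson interval. Sums over cells were given a 95% exact Poisson interval. Both cover counting error only. Depth ran from 16424 to 366882 UMIs per cell, which leaves an interval of 4.38% to 5.04% around the share of the poorest cell. Medians, quartiles and ranges describe the cells, and no p-value for a difference between groups was computed. No 2 cells had identical values. Of 561 pairs of cells, 1 agreed within counting error in both its exonic and its intronic total (2-sided exact binomial tests, both with an unadjusted p above 0.05), which does not show that both come from a single library because counts per gene were not compared.

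Before the data were examined, these other settings were fixed: exonic or intronic UMIs only, minimum depths of 1000, 5000 and 10000 UMIs, the median or mean over cells in place of the pooled share, and leaving out each cell in turn. A median or total that stayed within 1.5 times its value was counted as unmoved, and a pooled share if it stayed inside its interval. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.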

Results

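Single tumor cells of 2 established human cell lines were profiled by Smart-seq3, a full-length single-cell RNA-seq method in which the 5' end of each captured molecule carries a unique molecular identifier (UMI). 22Rv1 is a prostate carcinoma line and A375 is a melanoma line. Cells of each line had been mixed into blood of healthy people and then recovered by depleting blood cells and capturing tumor cells. The labels describe 23 recovered 22Rv1 cells and 11 recovered A375 cells, each a GEO sample of its own. They name no culture, blood donor or recovery run, so each line stands for 1 sample however many of its cells were sequenced.

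The design implies a comparison of the transcripts of recovered 22Rv1 and A375 cells. That comparison was not made. The measured values used here are the total UMIs of 34 cells, each under an 8-letter code, and 0 of the 34 codes occur in the sample labels. No cell was therefore assigned to 22Rv1 or A375, and the values are given over all cells as medians and ranges without a test. Counts of single genes were not analysed here, so no gene has an expression value. This covers the melanocyte genes MLANA and PMEL, the prostate gene KLK3, the epithelial gene EPCAM and the leukocyte gene PTPRC, which encodes CD45. How many blood cells were among the recovered cells was likewise not analysed here.

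The first measure was the number of UMIs counted in each recovered cell, which depends on the RNA captured and on how deeply its library was sequenced. All 34 cells gave more than 10000 UMIs. The median was 41188.5 UMIs per cell from exons and introns together, with quartiles of 27519.2 and 64042.8. The poorest cell, coded QTTETCCG, held 16424 UMIs and the richest, coded TARDYPHK, held 366882, which is 22.3 times as many. Exonic UMIs alone had a median of 38081 and ran from 15669 to 298904. Intronic UMIs had a median of 1920.5 and ran from 369 to 76049, a 206-fold range. Over all cells, 2480794 UMIs were counted (95% exact Poisson interval 2477708 to 2483883), of which 2155612 were found in exons (2152735 to 2158492) and 330659 in introns (329533 to 331788). The intervals cover counting error only and say nothing about the spread between cells.

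In ascending order, the cells held 16424, 17411, 17912, 21221, 23297, 25231, 25311, 26635, 27350, 28027, 29620, 30661, 31785, 31873, 37142, 39128, 39556, 42821, 45479, 48180, 49099, 50641, 56368, 59703, 60424, 65249, 76387, 79017, 80693, 80832, 236515, 270250, 343670 and 366882 UMIs from exons and introns together. The 4 richest cells held 49.1% of all UMIs and made up 11.8% of the cells. The other 30 cells lay between 16424 and 80832 UMIs, with a median of 38135.

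**Figure D1:**
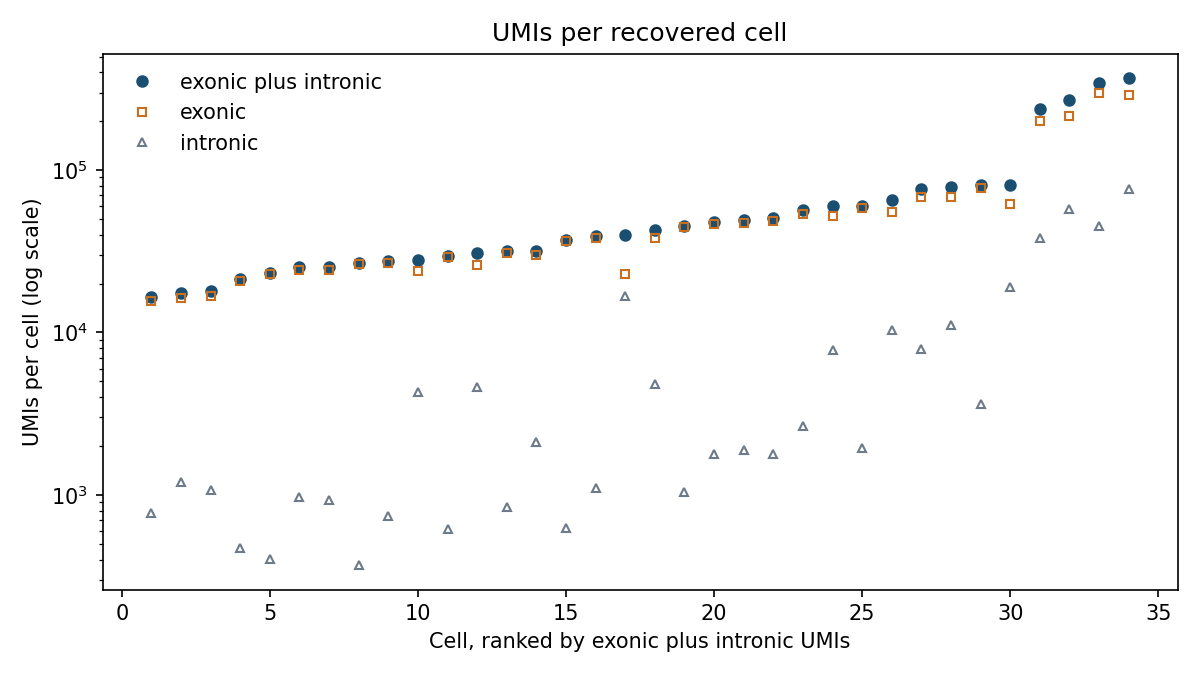
UMIs per cell on a logarithmic axis for the 34 cells, ranked by their exonic plus intronic UMIs; filled circles give exonic plus intronic, open squares exonic and open triangles intronic UMIs. The 4 cells on the right lie between 236515 and 366882 UMIs, above the other 30 cells, which reach 80832.

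The second measure was the share of a cell's UMIs assigned to introns, which are present in unspliced transcripts of the nucleus and are largely removed from cytoplasmic messenger RNA. The intronic share differed widely between cells. Its median was 4.71% of a cell's UMIs, with quartiles of 2.92% and 13.9%. The lowest share was 1.39% (95% exact Clopper-Pearson interval 1.25% to 1.53%), in the cell coded OVPXIQNR with 26635 UMIs. The highest was 42.4% (41.9% to 42.9%), in the cell coded WESPULJH with 39556 UMIs. This is a 30.6-fold difference between cells that were both below the median in UMIs. Without the cell coded WESPULJH the highest share was 23.5% and the range 16.9-fold.

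In the order of the totals above, the intronic shares were 4.70, 6.94, 5.95, 2.23, 1.73, 3.86, 3.65, 1.39, 2.71, 15.4, 2.07, 14.98, 2.65, 6.65, 1.69, 2.82, 42.4, 11.3, 2.29, 3.68, 3.88, 3.52, 4.72, 13.1, 3.21, 15.8, 10.4, 14.1, 4.49, 23.5, 16.2, 21.2, 13.2 and 20.7%. The 95% interval of a single cell was narrow beside these differences: it ran from 13.1% to 13.3% in a cell of 343670 UMIs and from 4.38% to 5.04% in the cell with 16424. The 4 richest cells had intronic shares of 13.2% to 21.2%. Among the other 30 cells the median share was 4.18%, and 9 of them had a share of 10% or more. Those 9 cells held 28027, 30661, 39556, 42821, 59703, 65249, 76387, 79017 and 80832 UMIs. Shares of 10% or more were thus more common at higher joint totals, although the cells with 60424 and 80693 UMIs had shares of 3.21% and 4.49%. The joint total includes the intronic UMIs, so a high intronic share by itself moves a cell up in this order. The cell with 39556 UMIs, for example, held 22947 exonic UMIs. Pooled over the UMIs of all cells, the intronic share was 13.3% (13.29% to 13.37%), higher than in 25 of the 34 cells. The 4 richest cells contributed 65.6% of the intronic UMIs to it.

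**Figure D2:**
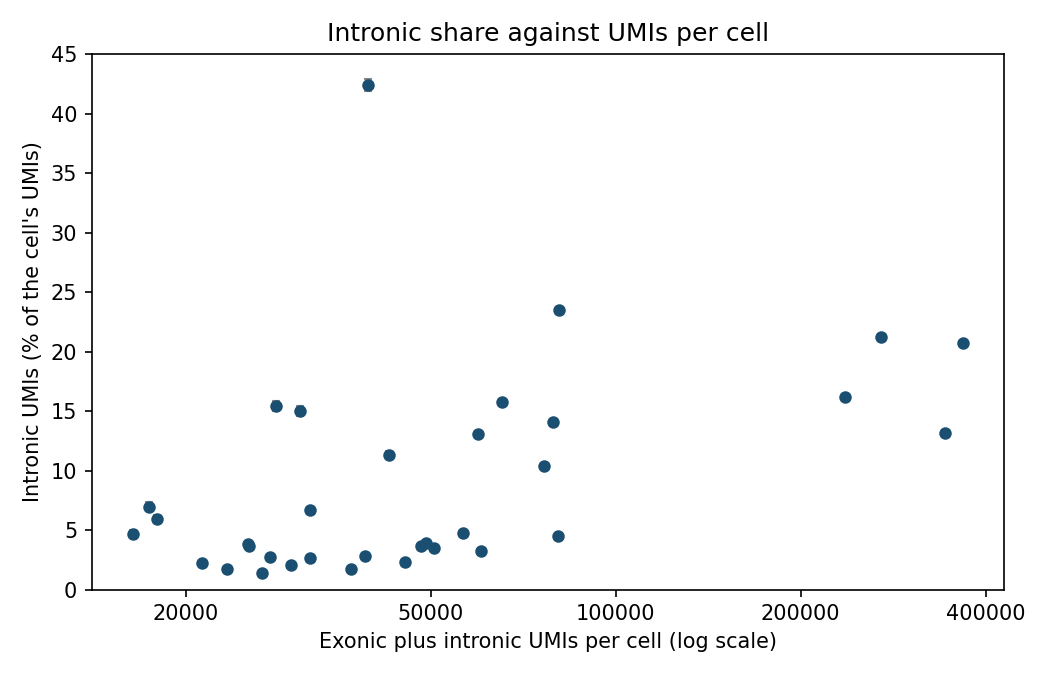
Intronic UMIs as a percentage of the cell's UMIs (linear axis) against exonic plus intronic UMIs per cell (logarithmic axis); each point is 1 of the 34 cells and bars are 95% exact Clopper-Pearson intervals, mostly smaller than the points. The highest point, at 42.4%, belongs to a cell with 39556 UMIs, and the 4 cells on the right lie between 13.2% and 21.2%.

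The spread was also seen at similar exonic depth. When the 34 cells were ranked by exonic UMIs, the 33 pairs of neighbours differed by a median of 2.19-fold in intronic and 1.04-fold in exonic UMIs. The largest difference in intronic UMIs was between the cells coded OMWHNTND and WESPULJH. Their exonic totals were 22903 and 22947 UMIs, whereas their intronic totals were 402 and 16764 UMIs, a 41.7-fold difference. Without WESPULJH the median was 2.10-fold and the largest difference 12.4-fold. It was between the cells coded EXXICGHZ and OVPXIQNR, with 26144 and 26279 exonic UMIs and 4594 and 369 intronic UMIs. Without the map from codes to lines, these differences were not compared between 22Rv1 and A375.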

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

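The alternatives without the 4 richest cells, without the highest and lowest of all cells, with a geometric mean and with UMIs absent from the exonic total were chosen after the data had been seen. The median of 41188.5 UMIs per cell stayed within 1.5 times its value under each alternative run except intronic UMIs only, which gave 1920.5. The sum of 2480794 UMIs was 2155612 with exonic UMIs only and 1263477 without the 4 richest cells, the 2 alternatives run for it. By the rule above, the former counted as unmoved and the latter as moved. The intronic share depended on how cells were weighted: 13.3% when pooled, it was 4.71% as the median and 9.03% as the mean over cells, and 8.99% pooled without the 4 richest cells. It was 13.1% with UMIs absent from the exonic total. Leaving out each cell in turn gave pooled shares from 12.04%, without TARDYPHK, to 13.6%. Both ends and the other alternative shares lay outside the pooled interval of 13.29% to 13.37% and counted as moved. That interval covers counting error only, a stricter rule than the 1.5 times above. The minimum depths of 1000, 5000 and 10000 UMIs removed 0 cells and so tested nothing. The alternatives for ratios between lines, for genes and for blood cell transcripts were not run, since no cell was assigned to a line and counts per gene were not used. No paired analysis was possible because the labels name no culture, blood donor or recovery run that could link cells of different lines. Counting error on a single cell's intronic share was small beside the differences between most cells. Reads per cell were not analysed here, so what sequencing depth limits is not known.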

Other observations

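All tests in this part were chosen after the values had been seen, and all are conditional on the 34 codes being the 34 labelled cells. The UMIs per cell fell into separate ranges. The widest gap between neighbouring cells was 2.93-fold, from 80832 to 236515 UMIs, and the next widest was 1.27-fold. Above it lay 4 cells with 236515, 270250, 343670 and 366882 UMIs, which is 6.20 to 9.62 times the median of the other 30 cells. In the intronic share the widest gap, 1.81-fold, set 1 cell at 42.4% apart from the other 33 cells, which reached 23.5%. The next widest, 1.498-fold, lay between 6.94% and 10.4%, with 21 cells below and 13 above. Of the 30 cells with fewer UMIs, 9 lay above it.

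The 4 cells with the most UMIs were weighed against 1 explanation. If the cell line alone decided on which side of the gap a cell fell, 11 or 23 cells would lie above it, but 4 did, so at least a part of the separation has another source. More than 1 cell in a well, larger cells, a higher yield of reverse transcription and deeper sequencing of these libraries remain open and untested, as does a line as part of the cause.

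The spread of the intronic share between cells was weighed against 2 explanations. If depth, measured as UMIs per cell, alone set the share, cells next to each other in exonic UMIs would have nearly equal shares. Their median log2 difference was 0.875 of that between all pairs (1.21 against 1.39). The ratio was 0.837 when the cells were ordered by the joint total of exonic and intronic UMIs instead. A ratio above 0.5, a cutoff set after the values had been seen, was taken to argue against this explanation. These values argue against depth so measured as the only source but leave it open as a part of the cause. Sequencing depth itself was not weighed, since reads per cell were not analysed here. The 4 richest cells had shares of 13.2% to 21.2%, and the other 30 cells had a median of 4.18%. If the line alone decided on which side of a gap in the share a cell fell, 11 or 23 cells would lie above it. Above the 2 widest gaps lay 1 and 13 cells, so the line alone did not set the side of every cell. However, 13 is close to 11, so these counts cannot exclude that the line set the side of most cells at the second gap. The line as a part of the cause cannot be told apart from other sources, because 0 codes occur in the labels. A nuclear or damaged cell that lost cytoplasm, or genomic DNA in the library, might also raise intronic UMIs, and neither was tested, since both need counts per gene or the read alignments.

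The cells coded YXUEXVXU and ALJTGTRU had 24284 and 24397 exonic and 973 and 924 intronic UMIs, differences within counting error (exact binomial p = 0.612 and p = 0.270, unadjusted, the only pair of 561 with both above 0.05).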
